A study of Arabidopsis thaliana with 18 samples.

How the data were processed

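H3K9me2 was measured by chromatin immunoprecipitation and sequencing in roots of Col-0, suvh5 and suvh6, noninfected or infected with Heterodera schachtii, in 3 replicates for each of 6 groups. Nothing in the labels says whether replicates came from separate plates or plants.

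What was analysed are 6 broad peak lists made by the authors. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.39, Bowtie2 2.2.9, SAMtools 1.3.1, MACS2 and bedtools 2.29.2, with genome build TAIR10. The versions of FastQC and MACS2, the peak calling options, the treatment of reads with several alignments and the way the 3 replicates of a group entered a call are not given in the sources used here. For each peak, the deposited lists give a fold enrichment of the first-named group with the second-named group as control, with its computation and the scaling between groups not stated. It is not a plain ratio of the 2 groups. At the 28 intervals called in both directions in Col-0, folds were above 1 both ways (1.18 and 1.20 at chromosome 2, 1288 to 10160). The lists also give a −log10 p-value and a −log10 q-value of the broad peak, computed by the authors' peak caller. These were used only to describe, rank and filter peaks within a list. Depth per sample is unknown, so no interval for counting error could be given, and a list without a peak at a locus does not show that the mark was equal there.

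Each list was read as called in the first-named group with the second-named group as the control, and was assigned to groups from its name alone. The letters A and B stand for the mutants, and no label ties them to suvh5 or suvh6. The groups and comparisons, the tests, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. Because a list is a single call, no comparison uses the spread between replicates, and counts of peaks between lists were compared as values with no test.

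Positions were placed on the TAIR10.1 reference, whose chromosomes 1 to 5 have the TAIR10 lengths, with its RefSeq annotation of 27444 protein-coding genes, 4843 pseudogenes and 5612 noncoding genes. Of the pseudogenes, 4341 carry no note and 29 a note naming a transposon, so transposon genes were not separated from other pseudogenes and no transposon families are named. The 9 annotation classes were protein-coding gene body, coding exon, untranslated exon, intron, 1 kb upstream, pseudogene, noncoding RNA gene, no annotated feature, and gene-poor windows of 500 kb with under 25% of bases in protein-coding genes (36 windows, 15.1% of bases). A peak counted for a class with 1 bp or more of overlap. For no annotated feature, the whole peak had to lie in such sequence. Results are described for 5 classes, and the other 4 classes enter only the counts of tests. The calls past the 0.05 threshold numbered 51 of 54 class tests over all lists.

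Overlap with classes, between pairs of lists and with gene lists was tested by permutation. Peaks of the same lengths were placed 10000 times at random within their chromosome, and two-sided p-values were adjusted by the Benjamini-Hochberg method over 54 class tests, 15 pairs and 90 gene list tests. The smallest p these placements can give is 0.0002. Shares of peaks in a class were compared between 5 pairs of lists with Fisher's exact test, two-sided, adjusted over 45 tests. Lists that share Col-0 libraries share their chance values. Simulating that needs read counts, so the overlap of genes expected from independent lists is given in its place.

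The 15 gene lists were the H3K9 and DNA methylation machinery, immune receptors, receptor-like kinases and proteins, salicylic acid defence, jasmonate and ethylene signalling, auxin signalling and transport, cell wall modification, WRKY transcription factors, sugar and amino acid transporters, glucosinolate and camalexin synthesis, defensin-like peptides, F-box proteins, cell cycle and endoreduplication, photosynthesis as a process not specific to roots, and transposable element genes. A gene counted when its body or 1 kb upstream met a peak. Members were matched by symbol, synonym or annotation text, which let in some genes of other function: AT2G33830, a dormancy associated gene with the synonym DRM2, OASB, a cysteine synthase with the synonym ACS1, LFY, whose note mentions an F-box partner, and catalases among the transporters. The named genes were, per list, the protein-coding genes of the 15 highest ranked gene peaks by −log10 q, then fold and length, up to 4 members per gene list, SUVH4, SUVH5, SUVH6 and MIR778, and the 10 highest ranked genes shared by the 3 lists of infected Col-0. Many genes of the first kind lie in a chromosome 2 insertion of mitochondrial DNA and were summarised.

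Repeated sequence was measured as the share of 31-mers that occur more than once in the chromosomes (8.73% over all bases). Nuclear matches to the mitochondrial and plastid genomes came from BLAST+ 2.17.0 at 90% identity or more over 100 bp or more. GC-matched placement drew positions within 1 percentage point of each peak's GC content. The tolerance had to be widened for 14 of the 791 gained peaks and for 0 to 22 peaks in the other lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, samtools 1.23.1 and matplotlib 3.10.9.

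The tests were tested on simulated data with 100 lists of 353 peaks, the size of the list of infected Col-0 over mutant B, and 1000 placements. Without an effect, 1% of lists were called in the class test, 0% in the pair test and 4% in the gene list test. With 20% of peaks planted in the feature, 100% were called in each. Lists without an effect were drawn by the same random placement that the tests use, so low call rates were built in. Clustering of peaks, GC content and shared libraries were not simulated, and weaker effects were not tried.

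The other settings fixed at that stage were −log10 q of 2 or more, fold of 2 or more, lengths of 300 bp or more, removal of gene-poor windows, an overlap of 50% of the shorter peak, peaks within 500 bp, equal list lengths of 100 peaks, the class of the midpoint, gene-poor windows under 40% protein-coding, 2 kb upstream, gene body only, rotation of each chromosome's peaks, placement within gene-poor and other windows separately, and merging peaks within 5 kb. Added after seeing the data were 3 removals (peaks of 50% or more repeated 31-mers, peaks matching an organelle genome over 100 bp or more, and positions called in both directions in Col-0) and placement matched on coding exons or on GC. Each removal, also that of gene-poor windows, took out observed peaks only, and random peaks were still placed over whole chromosomes. The outcomes that the GC-matched test over coding exons and the test of distance to pseudogenes would need were written down after that, before each was run.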

Results

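Root tissue of Arabidopsis thaliana was profiled by chromatin immunoprecipitation and sequencing with an antibody against dimethylated lysine 9 of histone H3 (H3K9me2), a mark of transposons, pericentromeres and other silent chromatin. The 18 samples formed 6 groups of 3: wild type Col-0, suvh5 and suvh6, each noninfected at 15 days old or infected. Infected plants received 100 second-stage juveniles of the beet cyst nematode Heterodera schachtii, a parasite that induces feeding sites inside the root, when 10 days old and were collected 5 days after inoculation. SUVH5 and SUVH6 are histone methyltransferases that deposit H3K9me2. The values were 6 peak lists, each read as called in a Col-0 group with another group as the control, in the order its name gives. The labels do not say which list belongs to suvh5 and which to suvh6, so the mutants are called mutant A and mutant B. No list holds values per replicate and the read depth is unknown, so no value below has a spread between plants, and p-values cover only the placement of peaks along the genome. The fold enrichment and the −log10 q of each peak are the authors' deposited values, and the fold is not a plain ratio between groups. The lowest −log10 q in a list was 1.00 to 1.13. Its median in infected over noninfected Col-0 was 1.65, so genes named by fold alone can rest on weak peaks.

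The first question was how infection moved H3K9me2 in wild-type roots. In infected over noninfected Col-0, 791 peaks covered 796109 bp, with a median fold enrichment of 1.90. These gained peaks lay over genes: 719 of 791 (90.9%) overlapped a coding exon, against 439 expected from random placement, and 724 overlapped a protein-coding gene body, against 505. Pseudogenes were overlapped by 54 peaks (94.0 expected), and gene-poor 500 kb windows, which hold the pericentromeres, by 46 peaks (121 expected). Each of these 4 departures had an adjusted p of 0.0002 in a two-sided permutation test of peak placement, the smallest that 10000 placements can give. Among peaks with −log10 q of 2 or more, 262 in number, the deficits over pseudogenes and gene-poor windows were 0.993 and 0.809 times random placement and did not pass. The gained peaks had a mean GC content of 46.9%, against 36.0% for the chromosomes. Random placement matched on GC put 514 peaks over coding exons (95% range 488 to 539), fewer than the 719 observed.

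The gained peaks reached 1016 protein-coding genes, with each gene under a long peak counted. Outside mainly repeated and organelle-like sequence, the highest ranked was in MBD5 (AT3G46580), a methyl-CpG-binding domain protein, at chromosome 3, 17148397 to 17149327 (TAIR10), over 548 bp of coding exon and 383 bp of intron, with a fold enrichment of 3.18 and −log10 q of 41.0. Next came NIP2;1 (AT2G34390), a channel protein of the aquaporin family, at chromosome 2, 14514620 to 14515796, with 969 bp in coding exons and a fold of 2.78 (−log10 q 31.4). The same peak reached the upstream kilobase of AT2G34400, a pentatricopeptide repeat gene. AT2G28815, annotated as a 50S ribosomal protein, had a peak inside its coding exon at chromosome 2, 12367040 to 12367322 (fold 1.73). AT4G03565, of the cystatin superfamily, had one in its upstream kilobase at chromosome 4, 1586041 to 1586439 (fold 1.61), of which 119 bp matched an organelle genome. Higher ranked by q were AT2G08986, AT3G41762 and the chromosome 2 end genes AT2G01008, AT2G01021 and AT2G01023, in peaks of 85.4% to 91.3% repeated 31-mers and folds of 1.15 to 1.24. The positions of AT2G08986, AT3G41762 and the chromosome 2 end were also called in the reverse direction.

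A large part of the covered length lay in the nuclear copy of mitochondrial DNA on chromosome 2, 3239038 to 3509765. The gained peaks covered 91.6% of it and 1.7% of the 100 kb on either side, with a median fold of 1.47 inside. The longest gained peak, 70008 bp, lay there, and genes of this insertion such as AT2G07687, a cytochrome c oxidase subunit III copy, and AT2G07718, a cytochrome b copy, took many of the highest ranks. In all, 27 of the 791 peaks held 100 bp or more that matched an organelle genome, so reads from organelle DNA cannot be separated from nuclear H3K9me2 at these genes.

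**Figure D1:**
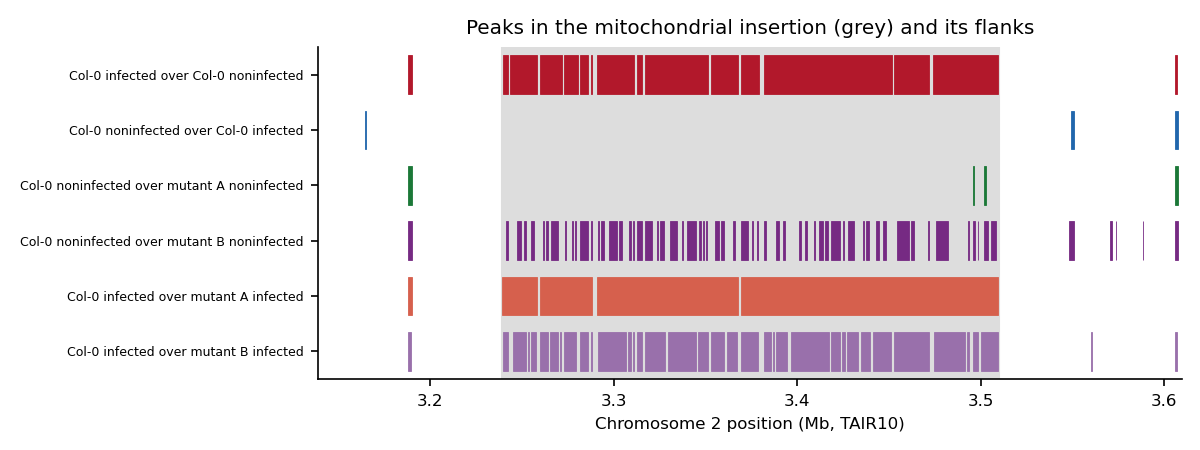
Peaks of each list (colored blocks, 1 line per list) across the mitochondrial insertion on chromosome 2 (grey) and its flanks, with position in Mb (TAIR10) on the horizontal axis. Gained peaks fill 91.6% of the insertion and peaks of noninfected over infected Col-0 cover none of it.

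**Figure D2:**
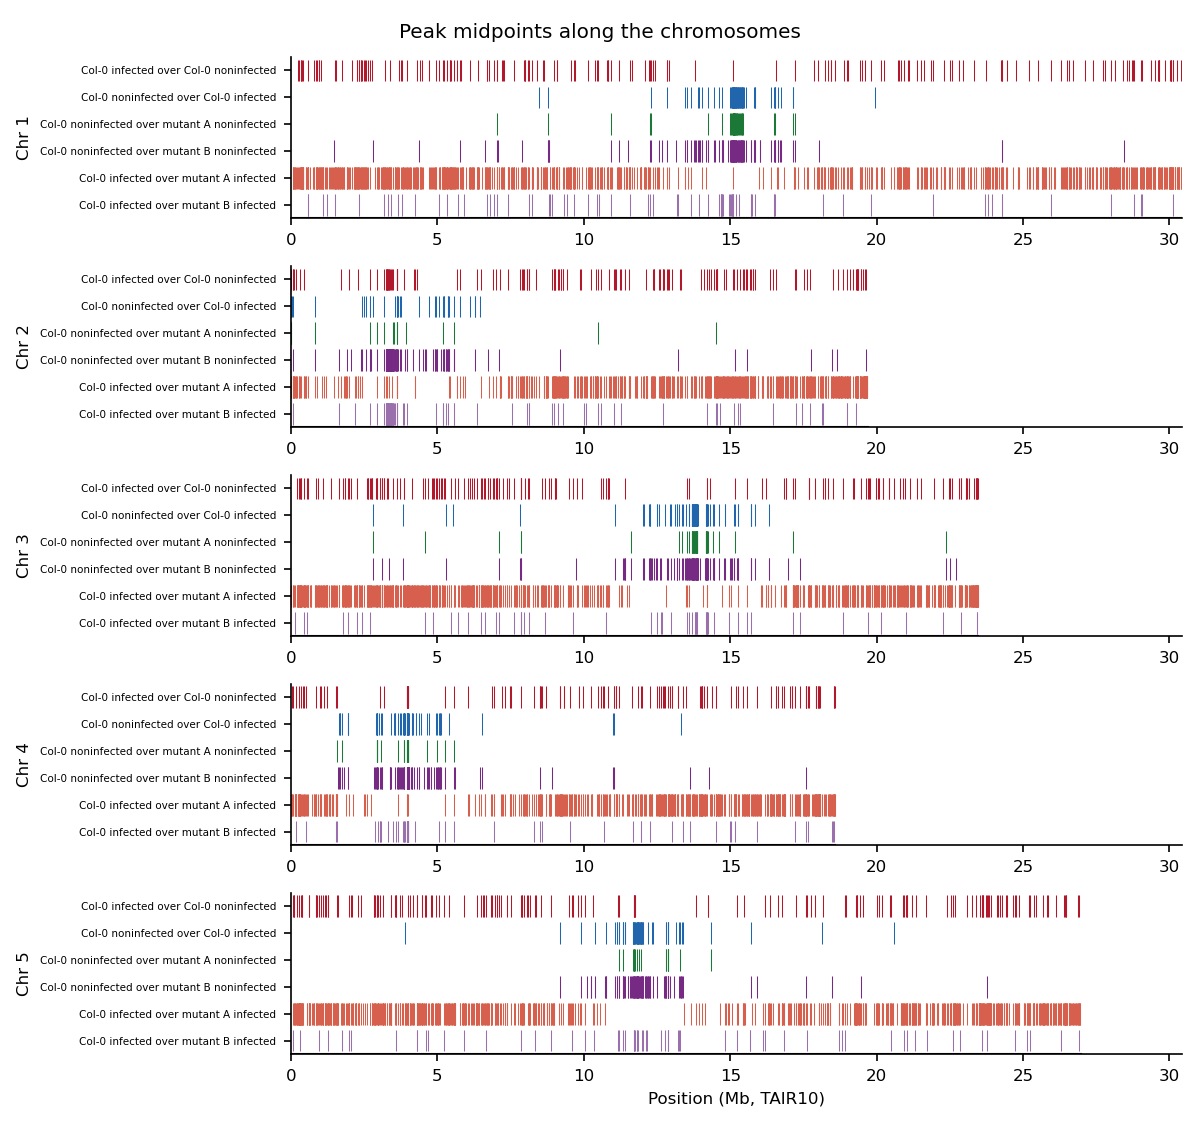
Midpoints of the peaks of each list along chromosomes 1 to 5, with position in Mb (TAIR10) on the horizontal axis and 1 line of ticks per list. Peaks of the list of noninfected over infected Col-0 cluster around the centromeres, while the 791 peaks of the reverse list and the 3106 peaks over infected mutant A spread along the arms.

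Among 15 gene lists, cell wall modification was the 1 list that passed the test in the gained peaks: 25 of 430 members had a peak in the body or 1 kb upstream, against 11.9 expected (adjusted p = 0.045 in a two-sided permutation test over 90 tests, and 0.009 adjusted over the list alone). Its highest ranked members were AT3G49220 (fold 2.00) and VGDH1 (2.08), both pectin methylesterase-like, AT5G23390, annotated as a polygalacturonase inhibitor (1.69), and the cellulose synthase CESA9 (2.01), which had its peak upstream. The call ended when random peaks were kept inside or outside coding exons as observed (14.3 expected, adjusted p = 0.126 in the permutation test), and only peaks of −log10 q of 2 or more gave 0.429 times random placement.

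The other 14 lists did not pass in the gained peaks. Receptor-like kinases and proteins had 19 of 409 members with a peak (13.7 expected), among them AT1G75640 (fold 2.05) and AT4G31250 (2.19). Immune receptors had 8 of 168 (6.36 expected), including RPS2, which recognises a bacterial effector (2.05). Salicylic acid defence had 2 of 24, the co-receptor NPR4 (upstream, 1.99) and CBP60G (1.85), with a −log10 q of only 1.75 and 1.19. Jasmonate and ethylene signalling had 4 of 102, with the ethylene regulators EIL1 (1.97), EIL2 (1.97), ERF13 (1.82) and ERF4 (1.80). Auxin signalling and transport had 11 of 212 (5.94 expected), including NPH4, the auxin response factor ARF7 (1.87), and GH3.3 (1.97). Sugar and amino acid transporters had 7 of 150 (4.48 expected), including STP6 (2.25) and STP1 (1.96). Numbers were 11 of 685 for F-box proteins, 2 of 71 for WRKY factors, 1 of 35 for glucosinolate and camalexin synthesis (CYP83B1, 2.02), 1 of 283 for defensin-like peptides, 2 of 45 for photosynthesis and 4 of 117 for transposable element genes. No peak met the 43 members of the H3K9 and DNA methylation machinery (1.96 expected) or the 56 of the cell cycle and endoreduplication list (1.58 expected).

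The reverse list, noninfected over infected Col-0, held 306 peaks over 412291 bp, with a median fold of 1.84. These lost peaks lay in silent chromatin: 258 of 306 (84.3%) were in gene-poor windows (46.8 expected) and 171 overlapped a pseudogene (39.6 expected), while 18 overlapped a coding exon (187 expected), each with an adjusted p of 0.0002 in the permutation test. Placement matched on GC brought the ratio to random placement from 5.51 to 3.44 in gene-poor windows and from 4.31 to 2.04 over pseudogenes, and both still passed. The lost peaks ended at 19951140 of 30427671 bp on chromosome 1, 6449489 of 19698289 on chromosome 2, 16335435 of 23459830 on chromosome 3, 13330593 of 18585056 on chromosome 4 and 20577277 of 26975502 on chromosome 5. Repeated 31-mers made up 50% or more of 223 of the 306 peaks. The annotation used here does not separate transposon genes from other pseudogenes. The share of peaks over coding exons was 85.0 percentage points higher in the gained than in the lost list (Fisher's exact test, two-sided, adjusted p = 3.81e-167), counting peaks as independent, which neighbouring peaks are not.

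Lost peaks met 29 protein-coding genes. The highest ranked without repeated sequence was SUT2 (AT2G02860), a sucrose transporter, with a peak at chromosome 2, 831250 to 831528, over 125 bp of coding exon and 154 bp of intron (fold 1.63, −log10 q 26.7). AT1G33860 (fold 1.79), MEE38 (1.61) and AT3G42160, of the pectin lyase superfamily (1.99), also had peaks of under 10% repeated 31-mers. AT1G40104 (1.49), AT1G43730, a reverse transcriptase gene (1.49), AT1G45223 (1.96) and GER2, a germin-like protein (upstream, 1.90), lay in peaks of 72.6% to 100.0% repeated 31-mers. The positions of AT1G33860, MEE38 and AT1G40104 were also called as gained, with folds of 1.75, 1.69 and 1.17. No F-box gene of 685 had a lost peak, against 6.92 expected (adjusted p = 0.045 in the permutation test, 0.0108 adjusted over the list alone), and the call ended under placement matched on coding exons (0.1208). The other 14 lists did not pass. Cell wall modification (AT3G42160), sugar and amino acid transporters (SUT2) and transposable element genes (AT1G43730) had 1 member each with a lost peak, and the remaining lists had 0, receptor-like kinases and proteins with 5.82 expected (adjusted p = 0.0828 in the permutation test, 0.0184 over the list alone).

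**Figure D3:**
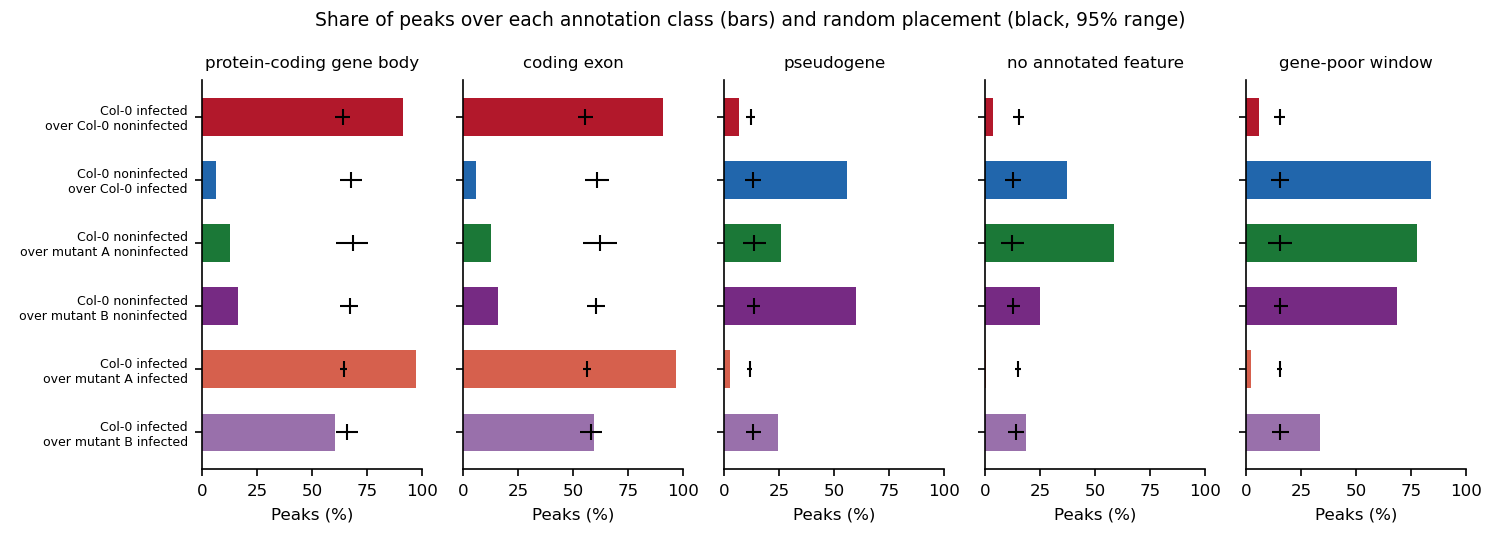
Percent of the peaks of each list over 5 annotation classes (bars), with the mean of 10000 random placements and its 95% range (black marks). Bars for coding exons reach 90.9% for infected over noninfected Col-0 and 96.7% for infected Col-0 over mutant A, against 5.88% for noninfected over infected Col-0.

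The second question was where peaks were called in noninfected Col-0 over the mutants. No list was called in a mutant over Col-0, infected or not. Of these peaks, 23 over mutant A and 20 over mutant B lay at positions called in both directions in Col-0. A peak over a mutant thus need not mean less H3K9me2 in that mutant. Over mutant A, 143 peaks were called, of which 111 (77.6%) lay in gene-poor windows (21.8 expected) and 18 overlapped a protein-coding gene body (97.8 expected). Over mutant B, 511 peaks were called, of which 350 (68.5%) lay in gene-poor windows (79.4 expected), 307 overlapped a pseudogene (67.8 expected) and 84 a gene body (342 expected). These departures had an adjusted p of 0.0002 in the permutation test. Pseudogenes made up 25.9% of the peaks over mutant A and 60.1% of those over mutant B (Fisher's exact test, adjusted p = 7.92e-13), and positions with no annotated feature 58.7% and 24.7% (adjusted p = 1.46e-13). Peaks of 50% or more repeated 31-mers were 118 of 143 and 279 of 511. Without them the excess over positions with no annotated feature turned to 0.547 times random placement for mutant A and 0.41 times for mutant B, and the differences between the mutants fell from 34.1 to 2.4 points for no annotated feature and moved from -34.2 to -12.5 points for pseudogenes, neither of which passed. Random placement still covered repeated sequence, so part of the turn against random placement is built in. Under GC-matched placement the ratios over mutant B fell from 4.41 to 2.35 in gene-poor windows and from 4.53 to 1.72 over pseudogenes, and both still passed.

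SUT2 led the unrepeated genes in both mutants, with a fold of 3.63 over mutant A (chromosome 2, 831044 to 831652, −log10 q 114) and 1.94 over mutant B (−log10 q 46.4). AT1G33790, a jacalin lectin gene (1.67 and 1.73), and AT1G30780, an F-box associated gene (1.94 and 1.76), had upstream peaks over both. Peaks over mutant A also met LBD22, a LOB-domain gene, in the 3′ untranslated region and the adjoining coding exon (fold 2.72), NIP2;1 with the edges of its gained peak (2.33), and MBD5. Over mutant B, no receptor-like kinase or protein of 409 had a peak (9.42 expected, adjusted p = 0.0045 in the permutation test, 0.0006 adjusted over the list alone), and 2 of 685 F-box genes did, AT1G30780 and AT1G12855 (11 expected, adjusted p = 0.0463 in the permutation test, 0.0108 over the list alone). Both calls ended in the permutation test matched on coding exons (7.39 and 9.42 expected, adjusted p = 0.099 and 0.126), and the F-box ratio went from 0.181 to 0.612 outside gene-poor windows and 0.44 without repeated peaks. The other 13 lists did not pass over mutant B, nor any of the 15 over mutant A. Members with a peak over mutant B were ARF19 among auxin genes, AT3G42160 for the cell wall (8.34 expected, adjusted p = 0.064 in the permutation test, 0.0128 over the list alone), SUT2 for transporters, CYP81F4, an indole glucosinolate enzyme, and 3 transposable element genes. Over mutant A they were SUT2, AT1G30780 and AT1G43730.

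The third question was the same comparison in infected roots. Over infected mutant A, 3106 peaks covered 2643998 bp, and 3003 (96.7%) overlapped a coding exon (1749 expected), while 65 lay in gene-poor windows (471 expected) and 86 over pseudogenes (360 expected). Over infected mutant B, 353 peaks were called, with 119 (33.7%) in gene-poor windows (54.2 expected) and 86 over pseudogenes (46.3 expected). All 5 of these departures had an adjusted p of 0.0002 in the permutation test. Coding exons were overlapped by 210 of the 353 peaks over mutant B, against 206 expected (adjusted p = 0.6611 in the permutation test), and gene bodies by 213, against 232 (adjusted p = 0.0328). For coding exons 5 other settings passed as an excess of 1.23 to 1.49 times, and peaks of −log10 q of 2 or more and GC-matched placement passed as deficits of 0.76 and 0.9 times. Under GC-matched placement the excess over pseudogenes turned for mutant B (94.5 expected), outside gene-poor windows the gene body deficit turned to 1.33 times, and without peaks of repeated 31-mers the excess in gene-poor windows turned to 0.789 times. Where peaks were removed by window or by repeats, random peaks still covered whole chromosomes, so part of those shifts is built in. Coding exons took 84.1 points more of the infected than of the noninfected peaks over mutant A (adjusted p = 2.83e-139, Fisher's exact test) and 43.8 points more over mutant B (8.37e-41). The Col-0 group changed along with the condition, so these differences can come from the Col-0 libraries alone.

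MBD5 and NIP2;1 led among genes without organelle-like or mainly repeated sequence over both infected mutants. MBD5 had a fold of 6.23 over mutant A (−log10 q 85.1) and 4.26 over mutant B (57.7), and NIP2;1 had 4.34 (57.5) and 3.31 (39.0). Over mutant A, AT2G28815 (2.24), SUT2 (1.95) and SERK5, a receptor-like kinase with 13 bp of its 3′ untranslated region in the peak (2.61), followed, while AT4G03565 (2.26), whose peak held an organelle match, ranked between MBD5 and NIP2;1. AT1G33790 had an upstream peak over mutant B (1.65).

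Over infected mutant A, receptor-like kinases and proteins had 88 of 409 members with a peak (49.9 expected, adjusted p = 0.0045 in the permutation test, 0.0006 adjusted over the list alone), led by SERK5. The chitin receptor LYK5 had a peak with a fold of 2.24. Cell wall modification had 72 of 430 (43.3 expected, permutation adjusted p = 0.0045, 0.0012 over the list alone), led by the pectinesterase AT5G66660 (2.42) and the pectin lyase-like AT3G57790 (2.33). Defensin-like peptides had 2 of 283, AT3G63360 and AT1G31772 (18.0 expected, permutation adjusted p = 0.0045, 0.0012 over the list alone). The peaks of these members had a −log10 q of 1.82 and 1.12. None of these 3 calls held in the permutation test matched on coding exons (adjusted p = 0.4161, 0.117 and 0.054) or with peaks of −log10 q or fold of 2 or more. Matching moved their ratios from 1.76 to 1.2, from 1.66 to 1.38 and from 0.111 to 0.138, while the q and fold limits gave 1.58 and 1.44, 1.81 and 1.69, and 0 and 0.

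The other 12 lists did not pass over infected mutant A. Photosynthesis had 11 of 45 (3.84 expected, adjusted p = 0.054 in the permutation test, 0.0288 over the list alone), jasmonate and ethylene signalling 19 of 102 (10.4 expected), with EIL1 (2.30), MYC2 (2.21) and OPR3 (2.06), and auxin signalling and transport 34 of 212 (21.7 expected), with NPH4 (2.15) and the auxin influx carrier LAX2 (2.07). Sugar and amino acid transporters had 26 of 150 (17.0 expected), with CAT8 (2.45) and STP6 (2.18), salicylic acid defence 5 of 24 (2.73 expected), with CBP60G (1.98) and PR5 (1.84), and immune receptors 23 of 168 (24.2 expected), with RPS2 (2.11). The PR5 peak had a −log10 q of 1.28. Members with a peak numbered 6 of 71 for WRKY factors (7.24 expected), with WRKY17 (1.97), 3 of 35 for glucosinolate and camalexin synthesis (3.84 expected), with CYP83A1 (2.21), 55 of 685 for F-box proteins (58.2 expected), 8 of 117 for transposable element genes (9.59 expected) and 1 of 56 for the cell cycle (5.91 expected). The H3K9 and DNA methylation machinery had 5 of 43 (6.72 expected), the highest ranked being AT2G33830 (2.02), a dormancy associated gene matched by a synonym. Others were the methyl-cytosine binding VIM1 (1.83), the silencing factor MOM (1.95) and SUVH3 (1.85). The peaks of VIM1, MOM and SUVH3 had a −log10 q of 1.83, 1.77 and 1.45. Over infected mutant B none of the 15 lists passed. Cell wall modification had 4 members with a peak, F-box proteins 5, receptor-like kinases and proteins 3, transporters 3, immune receptors 2, and salicylic acid (NPR4, 1.90), jasmonate and ethylene (OASB, a cysteine synthase matched by a synonym) and transposable element genes 1 each, and the other 7 lists 0. The NPR4 and OASB peaks had a −log10 q of 1.19 and 1.11.

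Positions were then compared between lists. Of the 791 gained peaks, 732 (92.5%) overlapped a peak of infected Col-0 over mutant A (35.4 expected), 143 of them also over mutant B, 21 over mutant B only and 38 (4.8%) over neither. Of the 306 lost peaks, 229 (74.8%) overlapped a peak of noninfected Col-0 over mutant B (3.41 expected) and 102 met peaks over both mutants, while 70 (22.9%) met neither. Between the noninfected lists, 124 of the 143 peaks over mutant A overlapped one over mutant B (1.71 expected). All these overlaps had an adjusted p of 0.0002 in the permutation test. Each pair shared the infected or the noninfected Col-0 libraries in the same role, which raises overlap by itself by an amount that peak lists do not give. In the 4 pairs with no shared group the overlap ran from 18.6% of the peaks over noninfected mutant B that met one over infected mutant A (3.43 times random placement) to 45.5% of those over noninfected mutant A that met one over infected mutant B (56.4 times). The first of these fell to 1.27 times without organelle-matching peaks.

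**Figure D4:**
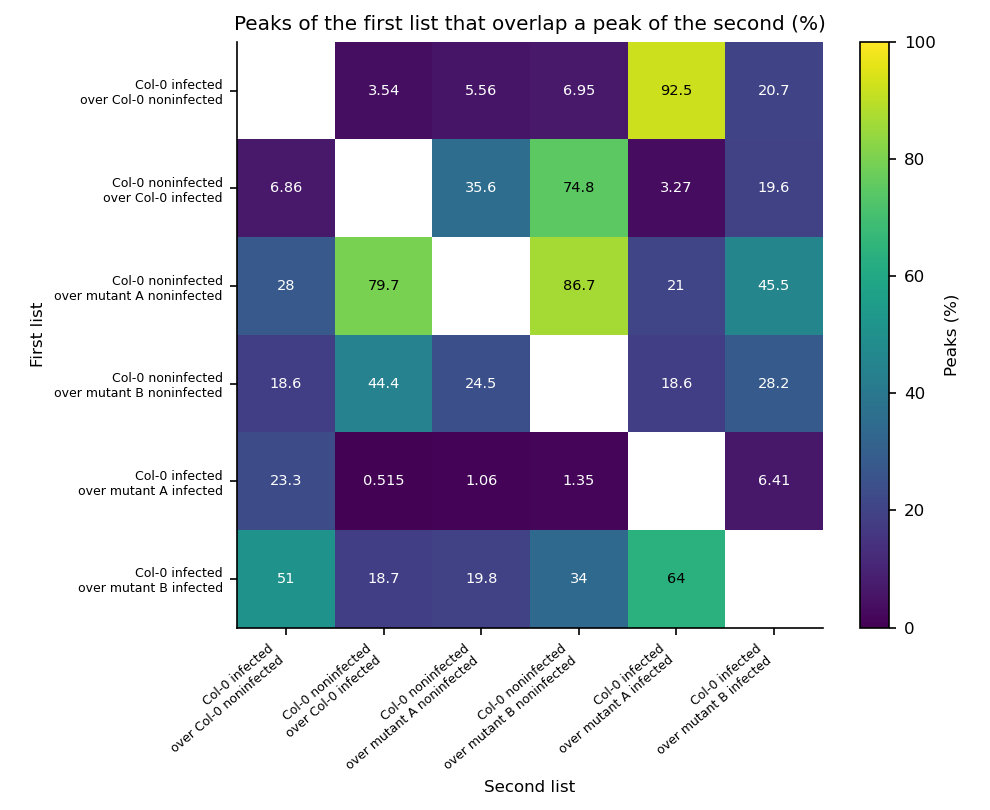
Percent of the peaks of the first list (vertical axis) that overlap a peak of the second list (horizontal axis) by 1 bp or more, as the color scale and the numbers give it. Gained peaks overlap those over infected mutant A at 92.5%, and peaks over noninfected mutant A overlap those over noninfected mutant B at 86.7%.

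In genes, 979 of those with a gained peak also had one over infected mutant A (146 if the lists were independent), and 234 genes had a peak in all 3 lists of infected Col-0. Ranked by the gained list, the first of these were AT2G08986, MBD5, NIP2;1, AT2G34400, AT2G07565, AT2G07687, AT2G07629, AT4G03565, AT2G07728 and AT2G07654, of which MBD5, NIP2;1 and AT2G34400 lay in peaks with neither mainly repeated nor organelle-like sequence. Genes that met the same long peak were each counted, as in the chromosome 2 insertion. The gained list covered 91.6% of it, and infected Col-0 over mutants A and B 97.9% and 79.0%. Part of the shared genes can thus come from a few peaks there, and no count without these genes is given. In opposite roles of a group, 10 of the 306 lost peaks overlapped a peak over infected mutant A (16.7 expected, adjusted p = 0.1012 in the permutation test). This ratio of 0.6 rose to 21.7 when the 100 highest ranked peaks of each list were compared. The other 3 such pairs lay at 11.6 to 26.4 times random placement, and lost with gained peaks, 21 of 306, at 4.62 times. Among peaks with a fold of 2 or more the values of 11.6 and 4.62 fell to 0, and without repeated peaks those of 26.4 and 4.62 fell to 0 and 2.18.

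No peak of the 6 lists lay on the bodies or upstream kilobases of SUVH4, SUVH5, SUVH6 or MIR778, the microRNA locus whose product targets SUVH5 and SUVH6. The nearest peak to SUVH5 (chromosome 2, 14822774 to 14826194) was 4823 bp away, in infected Col-0 over mutant A. In the same list the nearest was 15446 bp from SUVH6 (chromosome 2, 9662638 to 9667038), 11411 bp from SUVH4 and 18680 bp from MIR778. The lists therefore give no H3K9me2 value at the mutated genes by which mutant A and mutant B could be told apart.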

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

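Every test in this part was chosen in advance, and the 3 contrasts below stand out because the same Col-0 over mutant contrast placed its peaks differently between conditions or between mutants, by Fisher's exact test on peaks. Over mutant A, the share of peaks over coding exons was 84.1 percentage points higher in infected than in noninfected roots (96.7% against 12.6%), and the difference in gene-poor windows was -75.5 points (2.09% against 77.6%). Over mutant B, the coding exon share was 43.8 points higher in infected roots (59.5% against 15.7%), and the difference in gene-poor windows was -34.8 points (33.7% against 68.5%). Within infected roots, the coding exon share over mutant A exceeded that over mutant B by 37.2 points, with -31.6 points in gene-poor windows. Adjusted p-values of these 6 two-sided Fisher's exact tests ran from 2.83e-139 to 1.15e-23. Neighbouring peaks are not independent and each list is a single call, so these p-values do not cover the spread between plants. The Col-0 group changed along with the condition, so differences between infected and noninfected lists can come from the Col-0 libraries alone. Within Col-0, gained and lost peaks differed the same way over coding exons (90.9% against 5.88%).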

How the results depend on the processing

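The 3 removals (repeated 31-mers, organelle matches, positions called in both directions) and placement matched on coding exons or GC were chosen only after the data were seen, though before their own use in the tests on GC-matched counts and distance to pseudogenes, and the other alternatives were planned. No paired analysis was possible because the lists hold no values per replicate, and for that reason neither the replicate block nor leaving out each replicate was run. Of 324 values for the 5 described classes, 283 kept their direction and their side of the threshold, as did 180 of 195 for pairs, 110 of 125 for differences and 46 of 84 for the 7 called gene list results. Peak counts stayed within 1.5 times in 24 of 42 values. For the changes below the cause was not tested, except where an alternative removes peaks by its construction. Settings that removed peaks in gene-poor windows or over repeats still placed random peaks over whole chromosomes. Their shifts toward genes and away from gene-poor or unannotated sequence are therefore partly built in. Unknown depth limits every list, since a weaker library gives fewer peaks.

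Peak counts moved as follows. The gained list went from 791 to 262 with −log10 q of 2 or more and 172 with fold of 2 or more. The lost list went from 306 to 169 and 36, to 48 outside gene-poor windows and 83 without repeated peaks. Noninfected Col-0 over mutant A went from 143 to 24 by fold, 32 outside gene-poor windows and 25 without repeats, and over mutant B from 511 to 273 by q, 58 by fold, 161 outside gene-poor windows and 232 without repeats. Infected Col-0 over mutant A went from 3106 to 1021 by q and 796 by fold, and over mutant B from 353 to 168 by q, 84 by fold and, outside gene-poor windows, 234.

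Class results are ratios to random placement. For gained peaks, pseudogenes went from 0.574 to 0.993 by q and 0.84 with placement within gene-poor and other windows, and gene-poor windows from 0.38 to 0.809 by q. Placement matched on GC lowered these ratios further, to 0.232 and 0.226. For lost peaks, no annotated feature went from 2.95 to 1.11 outside gene-poor windows and turned to 0.57 without repeats. Placement matched on GC moved pseudogenes from 4.31 to 2.04 and gene-poor windows from 5.51 to 3.44 for lost peaks, and from 4.53 to 1.72 and 4.41 to 2.35 over noninfected mutant B, with direction and call kept in all 4. It raised no annotated feature to 7.01 for lost peaks, 6.63 over noninfected mutant A and 4.79 over noninfected mutant B. Over noninfected mutant A, coding exons went from 0.203 to 0.64 without repeats, pseudogenes from 1.93 to 1.92 under rotation and 0.603, a reversal, within windows, and no annotated feature from 4.86 to 1.75 outside gene-poor windows and 0.547, a reversal, without repeats. Over noninfected mutant B, no annotated feature went from 1.94 to 1.51 by fold, and turned to 0.564 outside gene-poor windows, 0.41 without repeats and 0.998 within windows. The list over infected mutant B depended most on settings. Its gene bodies went from 0.917 to 1.06 by fold, 1.33 outside gene-poor windows, 1.31 without repeats and 1.11 within windows, all reversals, and no longer passed at 0.966 without positions called both ways, 0.987 by midpoint and 0.916 under rotation. Its coding exons, at 1.02, became 0.76 by q, 0.976 at 300 bp or more and 0.9 under GC matching, reversals, and passed at 1.23 by fold, 1.49 outside gene-poor windows, 1.47 without repeats, 1.38 by midpoint and 1.25 within windows. Its pseudogenes went from 1.86 to 1.44 by fold, 1.24 outside gene-poor windows, 1.33 without repeats, 1.13 within windows and 0.91, a reversal, under GC matching. Its no annotated feature class went from 1.35 to 1.14 by fold, 0.266 outside gene-poor windows and 0.289 without repeats (both reversals), 1.07 without positions called both ways, 1.17 by midpoint and 1.04 within windows, and its gene-poor windows from 2.19 to 0.789, a reversal, without repeats. GC matching raised its no annotated feature class to 3.15 and lowered its gene-poor windows to 1.53.

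Pair results are ratios too. Lost with gained peaks went from 4.62 to 0 by fold, 3.13 outside gene-poor windows, 2.18 without repeats and, by construction, 0 without positions called both ways. Matching on coding exons raised this pair to 8.52. Noninfected mutant B with gained went from 11.6 to 0 by fold. Lost peaks with infected mutant A, at 0.6, became 2.38 by q, 21.7 at equal lengths, 2.08 within windows and 1.41 matched on coding exons, reversals, and passed at 0.144 without positions called both ways and 0.414 within 500 bp. Lost peaks with infected mutant B went from 26.4 to 0 without repeats. Noninfected mutant B with infected mutant A went from 3.43 to 0 by fold, 1.27 without organelle matches and 6.55 matched on coding exons, and with infected mutant B from 26.8 to 17.0 by fold.

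Gene list calls were 7 of 90 tests, 0 by q, 0 by fold, 9 at 300 bp or more, 4 outside gene-poor windows, 4 without repeats, 7 without organelle matches, 6 without positions called both ways, 6 with 2 kb upstream, 9 with gene body only, 5 under rotation, 3 within windows and 0 matched on coding exons. Gained peaks in cell wall genes went from 2.09 to 0.429 by q and 0.835 by fold, reversals, 1.91 within windows and 1.75 matched on coding exons. Receptor-like kinases over infected mutant A went from 1.76 to 1.58, 1.44 and 1.2 by q, by fold and matched on coding exons, cell wall genes from 1.66 to 1.81, 1.69 and 1.38, and defensin-like peptides from 0.111 to 0, 0 and 0.138. F-box genes over noninfected mutant B went from 0.181 to 0.157 by q, 0 by fold, 0.612 outside gene-poor windows, 0.44 without repeats, 0.209 without organelle matches, 0.193 without positions called both ways, 0.191 under rotation, 0.406 within windows and 0.212 matched on coding exons. Counts of 0 for receptor-like kinases there and for lost F-box genes stayed 0 in every setting that ended the call, except 0.115 for lost F-box genes with 2 kb upstream.

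Among differences in percentage points, noninfected mutant A minus mutant B was -3.85 for gene bodies and became 2.71 merged, 6.69 without repeats, 1.83 without organelle matches and -8.16, now past the threshold, without positions called both ways. Coding exons went from -3.07 to 2.71 merged, 8.41 without repeats and 1.83 without organelle matches, pseudogenes from -34.2 to -12.5 without repeats, no annotated feature from 34.1 to 2.4 without repeats, and gene-poor windows from 9.13 to 1.31 merged, -6.31 without repeats, 1.22 without organelle matches and 9.25 without positions called both ways. For mutant B, infected minus noninfected in no annotated feature was -5.96, and passed at -7.58 without organelle matches and -7.45 without positions called both ways.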

Other observations

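The tests on repeated sequence, organelle DNA, the flanks of the insertion, the unrepeated lost peaks and the mean GC of exon-centred peaks were chosen only after the result was seen, while those on GC-matched placement and on distance to pseudogenes were written down after the peak lists had been examined but before their own results, the GC-matched one once the mean GC was known. Further positions of plastid and mitochondrial origin carried peaks in several lists. AT2G07565, a Ycf1 domain gene at chromosome 2, 3187879 to 3189844, had a fold of 1.65 in the gained list, 2.02 over infected mutant A and 1.41 over noninfected mutant A, and 1164 bp of its gained peak matched an organelle genome. Over noninfected mutant A, a peak of 862 bp on AT3G20362, which also met the upstream kilobase of the TRAF-like gene AT3G20370, matched an organelle genome over its whole length (fold 1.58). UBQ13, a ubiquitin gene, had such a peak inside an intron over noninfected mutant B (310 bp, fold 1.38).

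Peak edges recurred at 3 places in the lists of infected Col-0. The peaks of NIP2;1 at 14514620 on chromosome 2, of MBD5 at 17148397 on chromosome 3 and a peak at 13005174 on chromosome 4 began at the same base in all 3 lists, with folds at the last place of 2.05 over noninfected Col-0, 2.27 over mutant A and 1.93 over mutant B. These lists share the infected Col-0 libraries. Lists of noninfected Col-0 shared 1 start. Recurring edges were not confined to infected roots: over noninfected mutant A, the NIP2;1 peak had both edges of its gained peak. The SUT2 peaks over noninfected and over infected mutant A both began at 831044 on chromosome 2. No explanation for these edges was tested.

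Gained peaks lay over coding exons, and the tables argue against 2 explanations of that as the whole or main cause. Exon-centred peaks had a mean GC of 48.7%, above the 40.2% to 40.9% of placements matched on coding exons, so GC content stays open as a part of the cause. Peaks over coding exons were 1.4 times as many as in GC-matched placements (719 against a 95% range of 488 to 539). This counts against GC content as the whole cause. The same placements put 204 peaks in gene-poor windows, against 46 observed, so part of the excess restates that deficit. GC was not matched within the arms alone, where its part stays open. The median distance from exon-centred peaks to the nearest pseudogene, 44874 bp, lay above the matched range of 28875 to 38760 bp. This counts against spread of the mark from annotated pseudogenes as the main cause. Spread at some peaks, or from transposons not annotated as pseudogenes, stays open. Matched placements could also fall in gene-poor windows, where gained peaks were few, which may shorten the matched distances. A lower share of heterochromatin in the infected Col-0 libraries stays open: 67 of the 83 unrepeated lost peaks lay in gene-poor windows, against a 95% range of 7 to 20, but this restates the place of the lost peaks, and infected Col-0 peaks in gene-poor windows were fewer than placed at random over mutant A (65 against 471) and more over mutant B (119 against 54.2), where the ratio without repeated peaks was 0.789 and did not pass. Random placement for that ratio still covered repeated sequence, which lowers it in part by construction. A lower share of heterochromatin cannot be told apart from a redistribution of H3K9me2 in infected roots, the untested biological explanation the design names, because the share would differ between the same infected and noninfected groups and the lists hold neither depth nor replicates.

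Between infected and noninfected Col-0, 49 peaks (28 gained and 21 lost) lay at 28 intervals of 53450 bp called in both directions, 20 of them in tandem satellite arrays and 3 over ribosomal RNA genes. Repeated 31-mers made up a median of 82.9% of these peaks, against 0.0% of the other peaks of the 2 lists (one-sided permutation test within lists, p = 1e-05, the smallest that 100000 permutations can give), which is consistent with reads shared between repeat copies. Among the other lost peaks the median was 75.5%, so the contrast comes mainly from the gained list. Organelle DNA reads were argued against here, since 0 of the 49 peaks matched an organelle genome. No biological explanation was tested, and a gain or a loss alone does not give calls in both directions.

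Peaks over nuclear copies of organelle DNA were the third pattern. Outside the chromosome 2 insertion, gained peaks covered 58.5% of the 22241 bp of organelle-matching sequence, against at most 5.44% in the 95% range of random placements (permutation p = 0.0002, the smallest possible), while lost peaks covered 0%. Noninfected Col-0 over mutants A and B also covered 34.6% and 39.3%, as organelle DNA reads whose share differs between libraries, infected or not, would give. These matches pool plastid and mitochondrial sequence, 16575 and 279120 bp over all chromosomes, the latter mostly inside the insertion. Peaks over noninfected mutant A matched 8337 bp of plastid and 1635 bp of mitochondrial sequence. Mitochondrial reads in the insertion were therefore little tested here. The flanks of the insertion were covered at 1.7%, against 91.6% inside, short of the outcome set for a change of the mark across the surrounding heterochromatin. But lost peaks, 84.3% of them in gene-poor windows, covered only 2.13% of these flanks, and no list covered more than 4.08%. Such a change could thus miss the flanks, and the test does not decide on it. A change of H3K9me2 at the organelle copies themselves with infection, the biological explanation, stays open and untested, and coverage inside the insertion ranged over the 6 lists from 0% for lost peaks and 0.604% over noninfected mutant A to 97.9% over infected mutant A.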
